A study of Mus musculus with 6 samples.

How the data were processed

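RNA was measured in mouse germline stem cells, cultured spermatogonial stem cells of a wild-type GFP-marked DBA line, grown in a complete medium (control) or in a medium named for 8 mM pyruvate, with 3 libraries per group. Per the labels' protocols, RNA was isolated with TRIzol and a column kit and made into libraries with a stranded mRNA kit. The authors deposited whole-number counts per gene, with no normalization, in a table of 32285 genes named by Ensembl identifiers; 32158 of these have a symbol in the annotation used here. The submitters' processing notes name bcl2fastq 2.20, cutadapt 4.6, STAR 2.7.11a, HTSeq 2.0.5 and the build mm10. The annotation release, the strand setting of the counting and the filters are not given in the sources used here, so named genes whose exons overlap those of another gene are reported as uncertain. A further 3 columns of the table matched no sample used here and entered no step. No line of the table lacked a gene identifier (0).

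Library totals ran from 20918312 to 26413080 counts, so that the floor of 3 counts was 0.114 to 0.143 CPM, the count scaled to a fixed library total. Floors and counting intervals cover counting error only. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Counts of library pairs within each group differed by more than sampling noise, and each library was kept as 1 sample. The chi-square per gene ran from 3.07 to 46.8, the latter between control replicates 1 and 2.

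Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 14912, and scaled by TMM factors. The comparison used the quasi-likelihood test with robust dispersions, no covariate, and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the test's F value. Levels are TMM-normalized CPM, given as mean ± SD over 3 libraries. Log2 CPM of single libraries used a prior count of 2. Log2 fold changes are pyruvate minus control, as fitted by the quasi-likelihood model at edgeR's default prior count. Gene positions are those of GENCODE M21 on GRCm38. GC content and transcript length came from the same annotation and genome and were known for 14908 of the tested genes.

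Before the data were examined, 33 gene lists with 851 members, the tests, the alternatives and the rule for named genes were fixed. The lists cover glycolysis; pyruvate and lactate handling; alanine, glutamate and aspartate metabolism; the TCA cycle; nuclear-encoded and mitochondrial-encoded oxidative phosphorylation; serine, glycine and one-carbon metabolism; the integrated stress response; the endoplasmic reticulum unfolded protein response. They also cover mitochondrial stress and proteostasis, mitochondrial biogenesis and dynamics, cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation, the pentose phosphate pathway, hypoxia response, NRF2 antioxidant response, p53 targets and apoptosis, S phase, and G2 and M phase. The germ cell lists are stem cell and undifferentiated spermatogonia, differentiating spermatogonia, meiosis and pan-germ cell, beside cytosolic ribosomal proteins, interferon response, DNA methylation and histone modification, and naive and primed pluripotency. Marker lists for fibroblast and mesenchymal feeder cells, Sertoli cells, Leydig cells, endothelium, and macrophages and immune cells covered other cell types. Lists with at least 5 tested members were tested with limma 3.58.1 by camera at a preset correlation of 0.01, with adjustment over the 31 lists tested, and again with an estimated correlation and with fry. A member count "adjusted over the list alone" uses only that list's p-values.

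The text names up to 8 genes per direction with the largest log2 change among those past the threshold, with a mean of at least 5 CPM, separated groups and a symbol that is not a model, clone or ribosomal protein name. It also names the 3 members of lowest p in each list past its test, and 20 genes fixed by name. Other genes are said to be chosen after their values were seen.

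The alternatives were DESeq2's size factors, library totals, upper-quartile scaling, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were removal of each library's GC and length trend by splines with 5 degrees of freedom, voom with library quality weights, and an estimated list correlation combined with leaving out control replicate 2 or with the trend removal. The steps were tested on simulated counts for the 14912 genes of this comparison, which recovered 58 of 100 genes changed 1.5-fold and 95 of 100 changed 2-fold, with 8 unchanged genes called. A cholesterol list shifted by 0.35 in such counts was recovered with 0 other lists called. The genes changed 1.5-fold or 2-fold were drawn from those with a mean of at least 5 CPM. Counts were drawn independently for each gene, with no departing library and no GC trend. The recovery need not hold for the real counts, and the 0 does not test lists whose genes vary together.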

Results

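Gene expression was profiled by mRNA sequencing in cultured mouse germline stem cells, the in vitro counterpart of spermatogonial stem cells. A control group of 3 libraries came from cells in complete medium and a second group of 3 libraries from cells in medium named for 8 mM pyruvate. Library totals were 21714164, 26413080 and 20918312 counts in control replicates 1, 2 and 3 and 24749338, 25562768 and 21830090 in pyruvate replicates 1, 2 and 3. Between 19132 and 19683 genes had counts in each library, and 14912 of 32285 genes were tested. Control replicate 2 stood apart: on the first principal component, with 38.9% of the variance, it lay at 36.5 while the other controls lay at -4.12 and 0.81. Pyruvate replicate 1 lay at the other end, at -27.2. The second component, with 28.4% of the variance, placed control replicates 1 and 3 at -23.4 and -21.4, the pyruvate libraries between 9.84 and 15.1, and control replicate 2 at 7.33. Control replicate 2 was closer to pyruvate replicates 2 and 3 than to either other control. Its Pearson correlation of log2 CPM was 0.9869 and 0.9884 with control replicates 1 and 3. With pyruvate replicates 1, 2 and 3 it was 0.9815, 0.9901 and 0.9889.

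**Figure D1:**
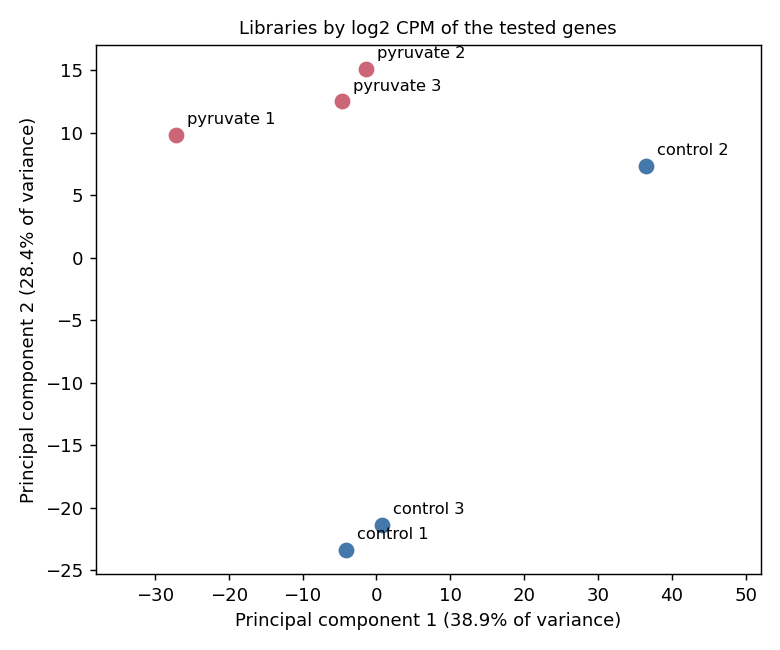
Positions of the 6 libraries on the first and second principal components of log2 CPM over the tested genes, with control libraries in blue and pyruvate libraries in red. Control replicate 2 lies at 36.5 on the first component, away from the other 5 libraries.

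The comparison of pyruvate medium with complete medium addressed how the transcripts of these cells differ when the energy source in the medium is changed, in a study of alanine metabolism and energy balance. Among the 8 genes that changed were a pair of related arrestin-domain genes that respond to glucose metabolites, which fell, an amino acid transporter, which fell, and an enzyme of cholesterol synthesis, which rose. Txnip, which restrains glucose uptake and binds thioredoxin, fell from 263 ± 16.3 to 107 ± 9.72 CPM (SD, n = 3 per group), 2.46-fold. Arrdc4, its close relative, fell from 52.8 ± 2.59 to 24.3 ± 1.89 CPM. Mvk, the mevalonate kinase of the cholesterol pathway, rose from 11.1 ± 1.95 to 25.04 ± 0.72 CPM.

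In all, 8 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 higher and 5 lower in pyruvate medium, 4 of them at least 2-fold. Txnip (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883) changed by -1.30 on the log2 scale (SE 0.091, adjusted p = 0.00525). Arrdc4 (ENSMUSG00000042659, chromosome 7, 68736995 to 68749241) changed by -1.12 (SE 0.094, adjusted p = 0.00773). Slc38a4 (ENSMUSG00000022464, chromosome 15, 96994820 to 97055956), an amino acid transporter whose paternal copy is expressed, fell from 105 ± 2.703 to 57.4 ± 0.60 CPM, or by 0.87 on the log2 scale (SE 0.072, adjusted p = 0.00773). Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), an imprinted growth factor, fell from 179 ± 6.07 to 112 ± 2.49 CPM, or by 0.67 (SE 0.069, adjusted p = 0.0186). Fam57a (ENSMUSG00000069808, chromosome 11, 76179671 to 76214827) fell from 38.9 ± 2.10 to 19.9 ± 1.76 CPM, or by 0.97 (SE 0.10, adjusted p = 0.0186). Pgbd5 (ENSMUSG00000050751, chromosome 8, 124369049 to 124439658), derived from a transposase, rose from 7.98 ± 0.26 to 15.9 ± 0.081 CPM, or by 0.99 (SE 0.097, adjusted p = 0.0186). Mvk (ENSMUSG00000041939, chromosome 5, 114444269 to 114460591) rose by 1.17 (SE 0.14, adjusted p = 0.0353). Lipg (ENSMUSG00000053846, chromosome 18, 74939322 to 74961263), the endothelial lipase, rose from 1.84 ± 0.19 to 5.19 ± 0.43 CPM, or by 1.49 (SE 0.16, adjusted p = 0.0202); its mean lies under the naming minimum and it was chosen after its values were seen. Exons of Txnip, Fam57a and Igf2 overlap annotated genes on the opposite strand, and those of Igf2 also a model on the same strand, so their counts are uncertain to that extent.

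**Figure D2:**
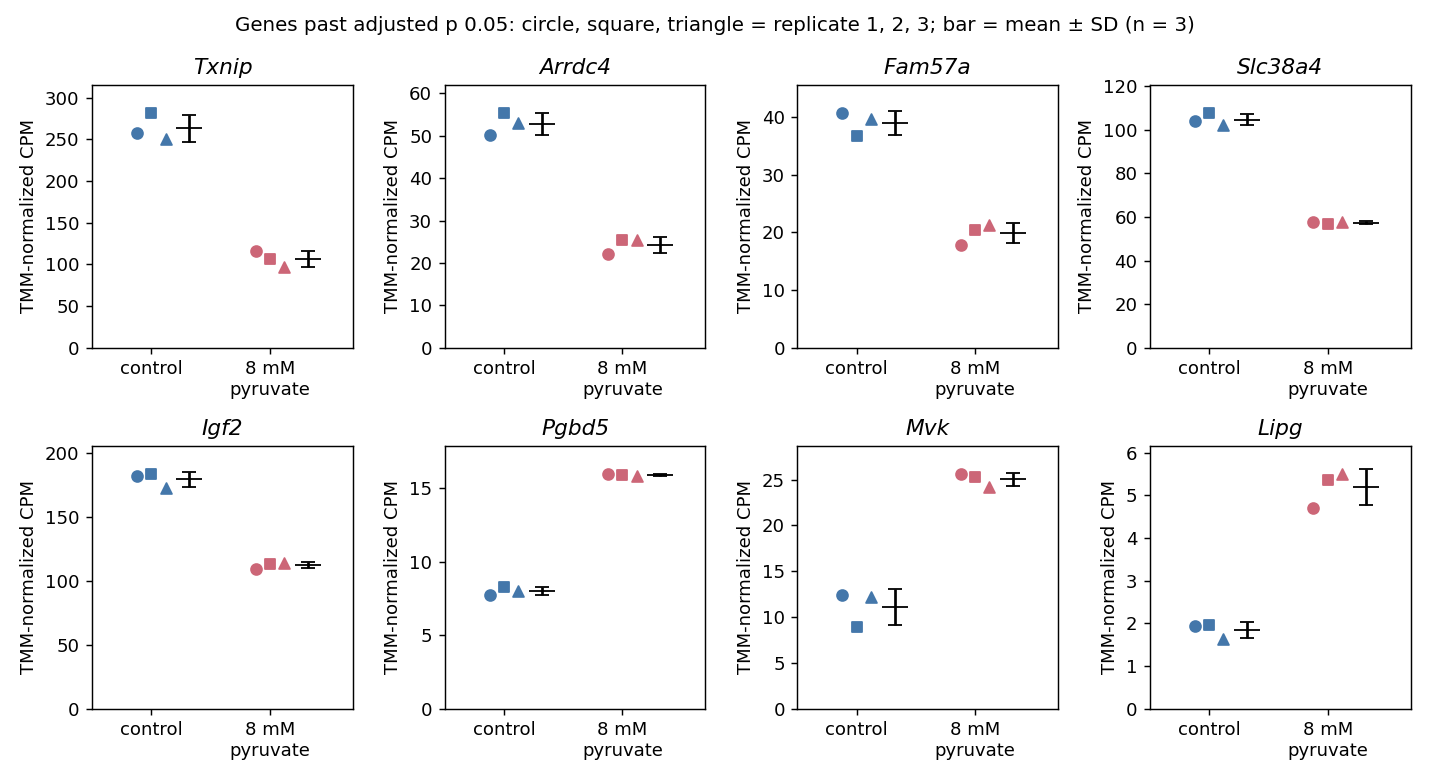
TMM-normalized CPM of the 8 genes past the threshold in each of the 3 control libraries (blue) and 3 pyruvate libraries (red), with the mean and SD of each group as a bar, on axes that start at 0. In each gene the libraries of both groups do not overlap, as with Txnip at 250 to 281 CPM in control and 97.2 to 117 CPM in pyruvate medium.

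The groups were separated in 22.5% of tested genes, and 2144 genes had an unadjusted p under 0.05. Chance gives 10% separated as an average over all splits of the libraries into 3 and 3. Genes that vary together can move a single split away from that average. The share in the other splits was not computed, so 22.5% against 10% decides nothing about the medium. The count of 8 rested on every library: it was 625 without control replicate 2, 3 without control replicate 1, 1 without control replicate 3, 1 without pyruvate replicate 1, and 0 without pyruvate replicate 2 or 3, where 1605 and 1661 genes had an unadjusted p under 0.05. DESeq2 called 288 genes with all libraries, and scaling by library totals or the upper quartile split the calls as 8 higher and 6 lower or 8 higher and 7 lower. All 8 genes were among the 625 and among the 288. Arrdc4 and Slc38a4 passed beside Txnip without control replicate 1, and Txnip alone without control replicate 3 or pyruvate replicate 1, while Mvk reached adjusted p = 0.309 without pyruvate replicate 2. Txnip was past the threshold in 4 of the 6 leave-one-out fits, and its adjusted p was 0.130 without pyruvate replicate 2 and 0.0716 without pyruvate replicate 3.

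Genes of cholesterol synthesis and uptake were higher together in pyruvate medium. Log2 fold changes of 25 of 25 members lay above 0, with a median of 0.36 and a mean of 0.45, and 17 members rose when adjusted over the list alone, against 1, Mvk, over all genes. Msmo1, a sterol demethylating oxidase, stood at 39.96 ± 2.67 CPM in control and 62.5 ± 1.52 in pyruvate medium (log2 0.64, SE 0.085, adjusted p = 0.0604 by edgeR over all genes). Lss, which closes the sterol rings, stood at 98.9 ± 1.43 and 143 ± 7.24 CPM (log2 0.54, SE 0.073, adjusted p = 0.0613), and its exons overlap a gene on the opposite strand. The list passed camera (adjusted p = 1.73e-22), with adjusted p = 0.0220 with an estimated correlation. Without control replicate 2 the median was 0.44 and 14 members rose over all genes, among them Msmo1 and Lss (adjusted p = 0.00220 and 0.00431), but the estimated-correlation test gave adjusted p = 0.127; with GC and length trends removed it gave 0.0568.

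Interferon response genes passed the same test upward, with 12 of 14 members above 0 and a median of 0.29 (camera adjusted p = 1.22e-06; adjusted p = 0.118 with an estimated correlation). Over the list alone 7 members rose and 1 fell, and over all genes 0 did, against 4 without control replicate 2, where Ifih1, Oasl2 and Isg15 passed (adjusted p = 0.0128, 0.0289 and 0.0258) and the list gave adjusted p = 0.474 with an estimated correlation. Ifih1, a sensor of double-stranded RNA, stood at 0.93 ± 0.11 CPM in control and 2.84 ± 0.46 in pyruvate medium (log2 1.59, SE 0.22, adjusted p = 0.0613). Oasl2 stood at 15.0 ± 1.46 and 33.5 ± 9.94 CPM (log2 1.16, adjusted p = 0.0913) and Isg15, a ubiquitin-like modifier, at 0.20 ± 0.14 and 1.40 ± 0.61 CPM (log2 2.76, adjusted p = 0.116). Isg15 lay close to the counting floor in control libraries, at 0.046 to 0.31 CPM. Macrophage and immune markers had 4 of 16 members tested, at most 5.70 CPM for Cd68, and were not tested as a list.

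The integrated stress response list, targets of the transcription factor ATF4, passed upward with 24 of 33 members above 0 and a median of 0.092 (camera adjusted p = 0.00208; adjusted p = 0.624 with an estimated correlation). Over the list alone 3 members rose, Ddit3, Trib3 and Herpud1, and over all genes 0. Ddit3, a transcription factor linked to stress-induced death, stood at 5.45 ± 0.80 and 9.67 ± 2.06 CPM (log2 0.83, adjusted p = 0.134), but its exons overlap other genes on both strands. With the GC and length trend removed Ddit3 passed edgeR's test over all genes (log2 0.78, adjusted p = 0.0470). Trib3 stood at log2 0.71 (adjusted p = 0.155) and Herpud1 at 0.62 (adjusted p = 0.160). Without control replicate 2 the list test gave adjusted p = 0.158.

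Genes of S phase and p53 targets passed downward. Of the S phase list, 26 of 27 members lay below 0 with a median of -0.18 (camera adjusted p = 1.22e-06; adjusted p = 0.504 with an estimated correlation), and 7 fell when adjusted over the list alone, against 0 over all genes. Without control replicate 2, 6 fell over all genes, among them Prim1, Rrm2 and Exo1 (adjusted p = 0.0230, 0.0340 and 0.0319), and the list gave adjusted p = 0.474 with an estimated correlation. Prim1, the small primase subunit, stood at 93.4 ± 0.84 and 72.6 ± 3.54 CPM (log2 -0.36, adjusted p = 0.123), Rrm2, a ribonucleotide reductase subunit, at 145 ± 7.78 and 101 ± 14.3 CPM (log2 -0.53, adjusted p = 0.124), and Exo1, a DNA exonuclease, at 173 ± 1.38 and 144 ± 2.16 CPM (log2 -0.27, adjusted p = 0.155). Of the list of p53 targets and apoptosis genes, 19 of 25 lay below 0 with a median of -0.23 (camera adjusted p = 0.000420; adjusted p = 0.504 with an estimated correlation), and over the list alone 6 fell and 1 rose, against 0 over all genes. Without control replicate 2, Ccng1, Zmat3 and Gtse1 fell over all genes (adjusted p = 0.0320, 0.0464 and 0.0177), and the list gave adjusted p = 0.474 with an estimated correlation. Ccng1, a cyclin induced by p53, stood at 60.6 ± 5.81 and 37.4 ± 6.58 CPM (log2 -0.70, adjusted p = 0.116), Zmat3 at log2 -0.60 (adjusted p = 0.134) and Gtse1 at log2 -0.33 (adjusted p = 0.162). The G2 and M phase list gave adjusted p = 0.0631 with a median of -0.088 (adjusted p = 0.624 with an estimated correlation), and passed downward with limma-voom (0.0181), with no filter (0.0355), without control replicate 1 (0.0386) and without pyruvate replicate 3 (0.0453).

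Cytosolic ribosomal protein genes passed upward and mitochondrial-encoded respiratory chain genes downward. Of 63 ribosomal protein genes, 59 lay above 0 with a median of 0.14 (camera adjusted p = 0.000357; adjusted p = 0.826 with an estimated correlation), and 0 rose over the list alone. Rps23, Rps7 and Rpl21 stood at log2 0.25, 0.22 and 0.25, with adjusted p = 0.391, 0.399 and 0.414. The list's median deviation was -0.32 in control replicate 2 against 0.078 and 0.052 in the other controls, and without control replicate 2 the test turned downward with adjusted p = 0.914; without pyruvate replicate 1 it gave 0.251. Of 13 mitochondrial genes 7 were tested and all 7 lay below 0 with a median of -0.26 (camera adjusted p = 0.00143; adjusted p = 0.624 with an estimated correlation). mt-Cytb stood at log2 -0.30 (adjusted p = 0.222), mt-Nd4 at -0.26 (adjusted p = 0.315) and mt-Nd1 at -0.32 (adjusted p = 0.338), and the list's median deviation was 0.35 in control replicate 2 against 0.037 and 0.017 in the other controls. The median deviation was 0.094 in pyruvate replicate 2, above control replicates 1 and 3. Without control replicate 2 the mitochondrial list gave adjusted p = 0.0268 with a median of -0.20 (adjusted p = 0.537 with an estimated correlation), and with all libraries it gave adjusted p = 0.123 with GC and length trends removed. Exons of Rpl21, mt-Nd1 and mt-Nd4 overlap annotated genes on the same strand, so their counts are uncertain. The other 6 mitochondrial genes had 0 to 7 counts per library, while mt-Co1 had 117743 to 223072.

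**Figure D3:**
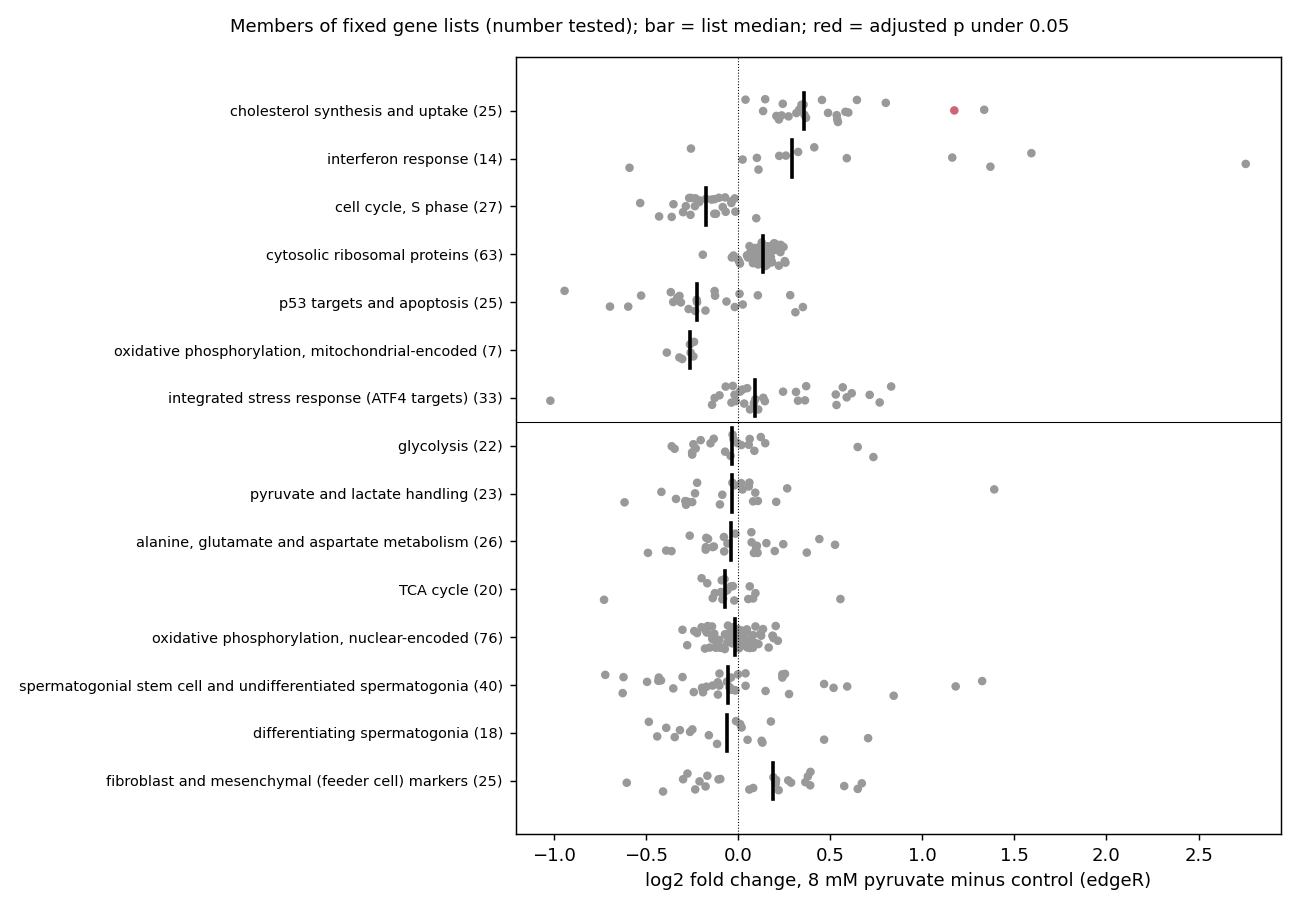
Log2 fold changes, pyruvate minus control, of the tested members of 15 fixed gene lists, with the list median as a bar and the number tested in parentheses; lists above the line passed camera at a preset correlation. Red marks the member past adjusted p 0.05 over all genes, and all 25 cholesterol genes lie above 0.

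Of the genes fixed by name in the pathways nearest to pyruvate and alanine, Txnip alone passed edgeR's test as first set, with all libraries. With the GC and length trend removed and all libraries kept, Got1 (log2 -0.42, adjusted p = 0.0345 in edgeR) and Slc16a1 (log2 -0.35, adjusted p = 0.0375) also passed, both downward. Slc38a1 and Slc38a2, amino acid transporters of the alanine, glutamate and aspartate list, were chosen after their values were seen. Both fell in that fit as well (log2 -0.52 and -0.33, adjusted p = 0.0146 and 0.0396 in edgeR). The values that follow are without trend removal. Of this list 2 members fell and 0 rose when adjusted over the list alone. Without control replicate 2, 2 fell over all genes, Slc38a1 (log2 -0.44, adjusted p = 0.0177 in edgeR) and Got1, and 0 rose. Gpt2, the mitochondrial alanine aminotransferase, stood at 36.4 ± 1.88 CPM in control and 34.6 ± 1.64 in pyruvate medium (log2 -0.077, SE 0.087, adjusted p = 0.727), and Gpt, its cytosolic form, at 4.30 ± 0.29 and 4.25 ± 0.40 CPM (log2 -0.016, SE 0.14). Got1, the cytosolic aspartate aminotransferase, stood at log2 -0.39 (adjusted p = 0.155), and at -0.45 with adjusted p = 0.0204 without control replicate 2. Ldha, the main lactate dehydrogenase subunit, stood at -0.25 (adjusted p = 0.325), and at -0.35 with adjusted p = 0.0298 without control replicate 2; Ldhb stood at 0.057. The pyruvate carrier genes Mpc1 and Mpc2 stood at 0.27 and 0.21, the kinases of pyruvate dehydrogenase Pdk1 and Pdk4 at -0.22 and 1.39 (Pdk4 at 0.26 and 0.69 CPM), the monocarboxylate transporter Slc16a1 at -0.42, the glucose transporter Slc2a1 at 0.12, hexokinase Hk2 at -0.25 and asparagine synthetase Asns at 0.085, with adjusted p between 0.222 and 0.714. Exons of Mpc1 and Slc2a1 overlap genes on the opposite strand, so their counts are uncertain. By camera, adjusted p was 0.697 for glycolysis, 0.267 for pyruvate and lactate handling (10 of 23 members above 0, and past the threshold downward by fry, which does not compare a list with other genes, adjusted p = 0.0277), 0.457 for alanine, glutamate and aspartate metabolism, 0.273 for the TCA cycle, 0.466 for nuclear-encoded oxidative phosphorylation, and 0.456 for the pentose phosphate pathway. Without control replicate 2, glycolysis and the TCA cycle (0.0268 each) and nuclear-encoded oxidative phosphorylation (1.45e-08) passed downward, with adjusted p = 0.474, 0.474 and 0.496 with an estimated correlation. Members past the threshold over all genes in that fit went both ways in glycolysis (2 higher, 3 lower) and the TCA cycle (1 higher, 2 lower). In nuclear-encoded oxidative phosphorylation 0 were higher and 5 lower.

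Other lists of metabolism and stress gave camera adjusted p of 0.0993 for fatty acid oxidation, 0.323 for fatty acid synthesis, 0.970 for serine, glycine and one-carbon metabolism, 0.147 for hypoxia response, 0.831 for NRF2 antioxidant response, 0.870 for the endoplasmic reticulum unfolded protein response, 0.273 for mitochondrial stress and proteostasis and 0.895 for mitochondrial biogenesis and dynamics. The one-carbon list had a median of -0.029, a mean of 0.089 and an upward test, and the unfolded protein response list a median of -0.024, a mean of 0.019 and an upward test. Mitochondrial stress and proteostasis passed downward without control replicate 2 (adjusted p = 0.0155; adjusted p = 0.474 with an estimated correlation). DNA methylation and histone modification gave 0.137, and naive and primed pluripotency 0.141, with 9 of 13 members above 0 and fry past the threshold upward (adjusted p = 0.0216). Over the pluripotency list alone 4 members rose and 1 fell, and without control replicate 2, 1 rose and 1 fell over all genes. Sox2, a pluripotency gene chosen after its values were seen, stood at 47.9 ± 2.59 CPM in control and 21.3 ± 4.95 in pyruvate medium. Its log2 fold change was -1.17 (adjusted p = 0.0613 in edgeR, and 0.00913 without control replicate 2). Without control replicate 1, fatty acid oxidation passed upward (adjusted p = 0.0215) and DNA methylation and histone modification downward (adjusted p = 0.0386). With all libraries and an estimated correlation, camera gave these lists adjusted p = 0.708 and 0.746.

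Genes of germ cell identity did not pass the test as first set, with all libraries, in either direction. Gfra1, the receptor subunit for the growth factor GDNF, stood at 348 ± 39.8 and 357 ± 51.4 CPM (log2 0.039, SE 0.12), with exons that overlap a gene on the opposite strand and counts uncertain to that extent, Etv5 at log2 -0.14, Zbtb16 at 0.24 and Ddx4, a germ cell RNA helicase, at 0.074. Zbtb16 passed without control replicate 2 (log2 0.45, adjusted p = 0.00813). Kit, the receptor that marks differentiating spermatogonia, stood at 40.4 ± 5.88 and 29.7 ± 13.7 CPM and Stra8, induced by retinoic acid, at 135 ± 15.8 and 108 ± 46.3 CPM, with pyruvate replicate 1 at 45.5 and 161 CPM and the other pyruvate libraries at 21.8 for Kit and at 86.4 and 76.4 CPM for Stra8. Camera adjusted p was 0.325 for stem cell and undifferentiated spermatogonia, 0.273 for differentiating spermatogonia, 0.483 for pan-germ cell genes and 0.697 for meiosis. The differentiating list passed downward without control replicate 2 (adjusted p = 0.0275; adjusted p = 0.496 with an estimated correlation) and without pyruvate replicate 1 (adjusted p = 0.00431).

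Markers of other cell types did not pass with all libraries. The fibroblast and mesenchymal list, which covers feeder cells, had 15 of 25 members above 0 and a median of 0.19 (camera adjusted p = 0.457), and passed upward without control replicate 2 (adjusted p = 0.0251; adjusted p = 0.474 with an estimated correlation). Its median deviation was 0.23 in control replicate 2 against -0.18 and -0.17 in the other controls. Sertoli cell markers gave adjusted p = 0.814 and endothelial markers 0.895, the latter with a median of -0.15, a mean of 0.060 and a downward test. Leydig cell markers had 2 of 10 members tested and were not tested as a list.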

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

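The settings chosen only after the results were seen were removal of the GC and length trend, voom with library quality weights, and an estimated list correlation combined with leaving out control replicate 2 or with the trend removal. Against 8 genes changed (3 higher, 5 lower, 4 at least 2-fold), library totals gave 14 (8 higher, 7 at least 2-fold), upper-quartile scaling 15 (8 higher, 8 at least 2-fold), and no filter 83 (52 higher, 31 lower, 20 at least 2-fold). The stricter filter gave 6, with 1 higher and 2 at least 2-fold, dropped Lipg from testing and gave Mvk adjusted p = 0.0558. DESeq2 gave 288 (161 higher, 127 lower, 28 at least 2-fold). Trend removal gave 197 (88 higher, 109 lower, 22 at least 2-fold) and library quality weights 2556 (1394 higher, 1162 lower, 172 at least 2-fold), the weight of control replicate 2 being 0.156. With the replicate number as a block 265 genes were called (151 higher, 114 lower, 33 at least 2-fold). Deviations of same-numbered libraries from their group means correlated at 0.31, 0.31 and -0.073. Control replicates 1 and 2 correlated best with their own number, and control replicate 3 with pyruvate replicate 1. Deviations within a group cancel out for each gene, so these correlations depend on each other and cannot decide whether the numbers pair the libraries. No block was used in the main test because the labels do not say that a shared number marks a shared culture. Leaving out a library gave 0 to 625 genes, 0 to 351 higher, 0 to 274 lower and 0 to 50 at least 2-fold. The 8 genes kept their direction in every setting that tested them, and DESeq2's size factors and limma-voom gave 8 genes. Causes of the 625 calls without control replicate 2 were tested and are weighed below. The effect of fewer samples or fewer genes tested was not separated, and the cause of the other moves was not tested.

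Of the lists, 4 higher and 3 lower became 1 and 0 with an estimated correlation, 0 and 0 with it and control replicate 2 left out or the trend removed, 3 and 2 with fry (cholesterol, interferon and S phase beside pluripotency and pyruvate handling, which camera did not call, and without the other 4 of camera's lists), and 2 and 8 with quality weights. G2 and M phase (0.0495, downward) and fatty acid oxidation (0.0411, upward) passed with the replicate block. Leaving out a library gave 3 to 5 higher and 3 to 8 lower. The ribosomal protein list turned downward without control replicate 2, its adjusted p running from 3.06e-08 to 0.914 over left-out libraries, with quality weights (0.123), and with an estimated correlation and control replicate 2 left out (0.987). Named genes near 0 changed sign: Etv5 ran from -0.25 to 0.012 over left-out libraries and stood at 0.020 with quality weights, Ldhb from -0.090 to 0.17 and at -0.18, Gfra1 from -0.026 to 0.16 and at -0.018 with the trend removed, and Gpt from -0.091 to 0.043 and at 0.015 with library totals. None of these 4 genes passed the test with all libraries in edgeR. Genes with a few counts, such as Isg15 and Pdk4, are limited by depth.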

Other observations

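The tests chosen only after the result was seen were those of depth, of fibroblast genes, of group differences in library means and of the departure of control replicate 2, those of the Hoxb, Hoxc, arrestin domain and both imprinted gene lists, and those with the GC and length trend removed. The genes of the Hoxb cluster, transcription factors of body patterning, lay lower together: 10 of 10 tested members were below 0, with a median of -0.57. Hoxb1 stood at log2 -1.02 (adjusted p = 0.0787 in edgeR), Hoxb9 at -0.77 (adjusted p = 0.0673) and Hoxb8 at -0.54 (adjusted p = 0.0817), and 0 members passed over all genes, against 9 without control replicate 2 and 7 with the GC and length trend removed; these genes were chosen after their values were seen. Adjusted over the 5 lists added later that had at least 5 tested members, which Hoxa and Hoxd genes did not, the list gave adjusted p = 0.0358 with an estimated correlation, but 0.0856 without control replicate 2 and 0.0528 with the GC and length trend removed, and since its members prompted the test it stays a hypothesis that they may have fallen together. Of the Hoxc cluster 9 of 9 members were below 0 with a median of -0.60 (adjusted p = 0.119 with an estimated correlation). Exons of Hoxb2, Hoxb3 and Hoxb5 overlap genes on the opposite strand, and those of Hoxc5 and Hoxc10 overlap each other, so these counts are uncertain. Abca1, a cholesterol exporter chosen after its values were seen, did not pass with all libraries (log2 0.58, adjusted p = 0.424 in edgeR), nor with the GC and length trend removed. It stood at 77.2 CPM in control replicate 2 against 32.1 and 35.8 in the other controls, and at log2 1.09 (adjusted p = 0.000665) without control replicate 2.

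The fall of Igf2 and Slc38a4 prompted a test of paternally expressed imprinted genes. Of 22 tested, 16 were below 0 with a median of -0.10. Igf2 and Slc38a4 themselves were the 2 that fell over all genes, against 3 members without control replicate 2 and 4 with the GC and length trend removed. By camera the list gave adjusted p = 0.00147 at the preset correlation and 0.201 with an estimated one. Both values count the 2 genes that prompted the test, so they are no independent evidence. The bound written for the list, a missed threshold, excludes nothing, so a shared fall may or may not exist. Maternally expressed imprinted genes gave adjusted p = 0.395 with an estimated correlation. In the arrestin domain family, Txnip and Arrdc4 fell while Arrdc1, Arrdc2 and Arrdc3 stood at 0.25, 0.41 and 0.59 (Arrdc3 passed upward without control replicate 2, at log2 0.89 with adjusted p = 0.00367, and with the GC and length trend removed, at 0.79 with adjusted p = 0.0146), so that the median was 0.25 while the list test pointed down. Its adjusted p was 0.0358 with an estimated correlation, 0.0856 without control replicate 2 and 0.0640 with the GC and length trend removed. The list was drawn up around Txnip and Arrdc4 after they had passed, so its p restates those genes and is no further evidence.

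More genes were called without control replicate 2, 625 against 8. A lower depth was argued against by its total of 26.4 M counts, above the median of the 6 libraries. RNA of fibroblast-like feeder cells stays open. Of the 5 most abundant fibroblast genes (Fn1, Col5a1, Col1a1, Twist1 and Col6a2, at -0.13 to 0.22), 0 were raised by the bound set. Exons of Fn1 and Col5a1 overlap other genes, so their counts are uncertain. Fewer than 2 raised had been written as the bound that would exclude feeder RNA, and it was met. The question was kept open after this was seen, since the list median was 0.40 higher than in the other controls. The mean level of these genes over the libraries, log2 CPM 4.06 to 8.23, could also hide a small share. GC and length bias stays open as part of the departure: across genes the deviations of control replicate 2 followed GC content with rho = -0.49, and with the trend removed 197 genes were called with all 6 libraries, below the 312.5 that would have marked it as the cause and above the 12 that would have excluded it. Of these, 171 were also among the 625. The other controls, replicates 1 and 3, followed GC content with rho = 0.45 and 0.32, but values within a group depend on each other. In pyruvate replicates 1, 2 and 3 rho was 0.38, -0.39 and -0.13, so a GC trend was not confined to control replicate 2. The log2 fold change of pyruvate minus control also followed GC content, with rho = 0.27.

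The library means of the cholesterol list on a centred log2 scale were -0.22 in control replicate 2, -0.22 and -0.23 in the other controls, and 0.19 to 0.27 in the pyruvate libraries.

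The higher level of cholesterol genes in pyruvate medium was weighed against the same bias. With the trend removed the list median was 1.18 times as large, and without control replicate 2 it was 1.21 times as large, and 25 of 25 members stayed above 0. The difference between the groups' library means was 0.45 before, 0.45 with the trend removed and 0.45 without control replicate 2, with SDs within groups of 0.031, 0.042 and 0.035, which argues against either as the source of the whole pattern, although the estimated-correlation test missed the threshold (adjusted p = 0.0568 and 0.127) where the bounds first set asked it to pass. The median went from 0.36 to 0.42 and 0.44, the SD over members from 0.30 to 0.28 and 0.25, and the estimated correlation between members from 0.018 to 0.089 and 0.055; the fit without control replicate 2 also has a library less, and the share of each in the larger p was not separated. Each pyruvate library had a higher list mean than each control library, with exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows, so an effect of the medium cannot be told apart from other differences between the groups. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, gave 8 genes, and the highest other gave 0.

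Pyruvate replicate 1 differed from the other pyruvate libraries in genes chosen after their values were seen. It had higher Kit, Stra8 and Sohlh1 (log2 differences of 1.06, 0.99 and 0.74), genes of differentiating spermatogonia, and lower Dusp6, Spry4, Lhx1 and Egr2 (-0.87, -0.80, -0.78 and -0.71), genes that respond to growth factor signals. With the GC and length trend removed the mean size of these and 3 further differences was 1.01 times as large, but as these genes were picked for their values in this library the test decides nothing, and the bias stays open. No biological explanation was tested, since the design names no group within the pyruvate libraries.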
